A study of Mus musculus with 18 samples.

How the data were processed

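RNA was measured in 18 libraries of mouse light zone germinal centre B cells sorted from the popliteal lymph node. Per the labels' protocols, sorted cells were lysed in a guanidine buffer, RNA was cleaned on SPRI beads and reverse transcribed, and libraries were made with Nextera XT, a kit that fragments and indexes cDNA with a transposase and does not mark strand. Reads were quantified with kallisto 0.43.0 and the genome build was GRCm38, per the submitters' processing notes. kallisto assigns reads to transcripts by pseudoalignment, so a read shared by near-identical copies, as for many ribosomal protein genes and the pseudogenes derived from them or for Sap18b and Sap18, is divided by an estimate. Values of such genes are therefore uncertain.

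The authors deposited 2 tables of values per gene and library, in a score that is the TPM (a share of transcripts scaled to a fixed sum) plus 1, per the file headers and a minimum of exactly 1. There are 6 libraries in the table for 12 h and 12 libraries in that for 24 h, over the same 30452 genes, and 1 was subtracted to recover TPM. The tables stand apart, so every difference between groups was taken within a table. The authors also deposited 4 tables of their own comparisons. Per the file headers these give for each gene the mean normalized count of each group, a signal pooled over libraries by the authors, a log2 fold change with its standard error on the log2 scale, and a p-value with an adjusted p-value. Those were used for comparison only, and the tool behind them is not given in the sources used here. Counts per library and values per transcript were not used here.

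Read depth per library is unknown, since TPM keeps no depth. The sums of the authors' mean normalized counts, per the deposited tables, were 17314931 for DECP and 17673356 for DECN at 12 h. At 24 h they were 7029809 for DECP, 6822477 for DECN and 6644095 for rapamycin-treated DECP. They are group means and give no depth of a single library. At 12 h between 13114 and 13597 genes had a TPM of at least 1 in a library, and at 24 h between 11128 and 12244.

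Groups were taken from the sample titles. The extraction protocol names 6 conditions with 3 replicates, whereas 5 groups of 3 or 4 libraries are held, so whether it describes these libraries in full is unknown. Gene identifiers were looked up in GENCODE release M21 for mouse (GRCm38), where 30123 of the 30452 were found, and coordinates are 1-based on that build. Analyses ran in R 4.3.3 with limma 3.58.1 and data.table (1.17.8), and plots in Python 3.11.15 with matplotlib 3.10.9. The design, the gene lists, the rule for naming genes and all but 23 of the alternatives were fixed before the data were examined.

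The test was limma with an intensity trend and empirical Bayes on log2(TPM + 1), over genes with a TPM of at least 1 in at least as many libraries as the smallest group. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. The 12 h comparison used 6 libraries, the 24 h comparisons all 12 in 1 fit, and the difference between the times all 18. "Rose" and "fell" are used of what passed the threshold. For the 30 gene lists, camera of limma was run with a preset correlation of 0.01 on lists with at least 5 measured members, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a set move on balance one way, were alternatives. The erythroid list, with 4 measured members at each time, and the stromal list at 24 h, with 4, were not tested. Ly75 was tested with a two-sided exact permutation test.

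Genes named are 18 genes fixed beforehand, the 8 largest rises and falls among genes past the threshold whose groups did not overlap and whose mean TPM was at least 5, and up to 4 members of each list with the smallest p. Immunoglobulin and T cell receptor segments, pseudogenes and genes named Gm or Rik were left out of the largest changes. For the difference between times the 5 largest of each direction were taken by the same filters, except non-overlap, which has no meaning there. Any other gene named was chosen after its values were seen.

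Alternatives covered the pseudocount (0.1 and 5), the filter (none, and TPM of at least 5), scaling (quantile, median centring, and TPM rescaled without immunoglobulin and mitochondrially encoded genes), array weights, no trend, a 2-fold minimum, the replicate number as a block, the second index as a term, only the groups compared, and each library left out in turn. Added after the data were seen were TPM rescaled without ribosomal protein genes, removal of a trend on transcript length, libraries of a single second index, further scalings and index settings for lists, and left-out libraries for Ly75. The pipeline was tested on simulated data with 200 changed genes per comparison. Of those changed 4-fold it recovered 22.7% for the 12 h comparison (13429 genes), 71.2%, 75.8% and 63.6% for DECP against DECN, rapamycin against DECP and rapamycin against DECN at 24 h (12783 genes), and 18.2% for the difference between times (11848 genes). Of those changed 2-fold it recovered 1.49%, 20.9%, 10.4%, 26.9% and 2.99% in the same order, so that counts of called genes understate smaller changes, above all at 12 h. With Benjamini-Hochberg adjustment recovery depends on the share of genes changed. These percentages hold for 200 changed genes and need not hold in the real data.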

Results

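Gene expression was measured by RNA sequencing in germinal centre B cells of mice, sorted as light zone cells (high CD83, low CXCR4) from the popliteal lymph node. The cells carried the B1-8hi receptor, a heavy chain that gives binding to the hapten NP. Hosts primed with ovalbumin 2 weeks earlier received a mixture of 15% DECP cells, Ly75 wild type per the labels, and 85% DECN cells, labelled as Ly75 knockout. Ly75 encodes DEC205, an endocytic receptor. After immunisation with NP-ovalbumin, an antibody to DEC205 joined to ovalbumin was given on day 6, a design meant to deliver antigen to DECP cells. Delivery itself was not measured here. At 12 h after the antibody 3 libraries of DECP and 3 of DECN cells were made. At 24 h there were 4 of DECP, 4 of DECN and 4 of DECP cells from hosts given rapamycin, an inhibitor of the kinase complex mTORC1, at 2.5 mg/kg with the antibody. The labels do not say which libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. Values are TPM, the depth of single libraries is unknown, and the 12 h and 24 h values stand in separate tables.

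Ly75 was 3.47-fold higher in DECP than in DECN cells at 12 h and 2.80-fold higher at 24 h, but was not absent from DECN cells. At 12 h its level was 32.6 ± 6.80 TPM in DECP (SD, n = 3) and 9.40 ± 0.816 in DECN (n = 3, highest 10.2). The exact permutation p was 0.1, the smallest that 3 against 3 can give. At 24 h it was 14.1 ± 3.28 TPM in DECP (n = 4, lowest 10.3) and 5.01 ± 1.67 in DECN (n = 4, highest 6.66). There the exact permutation p was 0.02857, the smallest possible for 4 against 4, and 0.0571 without DECN replicate 4. Rapamycin-treated DECP cells stood at 12.6 ± 4.65 TPM (n = 4), above DECN (exact permutation p = 0.02857) and not separable from untreated DECP (exact permutation p = 0.6). The gene (ENSMUSG00000026980) lies on the reverse strand of chromosome 2, 60292103 to 60383303 in GRCm38. Values per gene cannot show which part of Ly75 the reads of DECN cells came from, since transcript values are not held and were not analysed here.

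**Figure D1:**
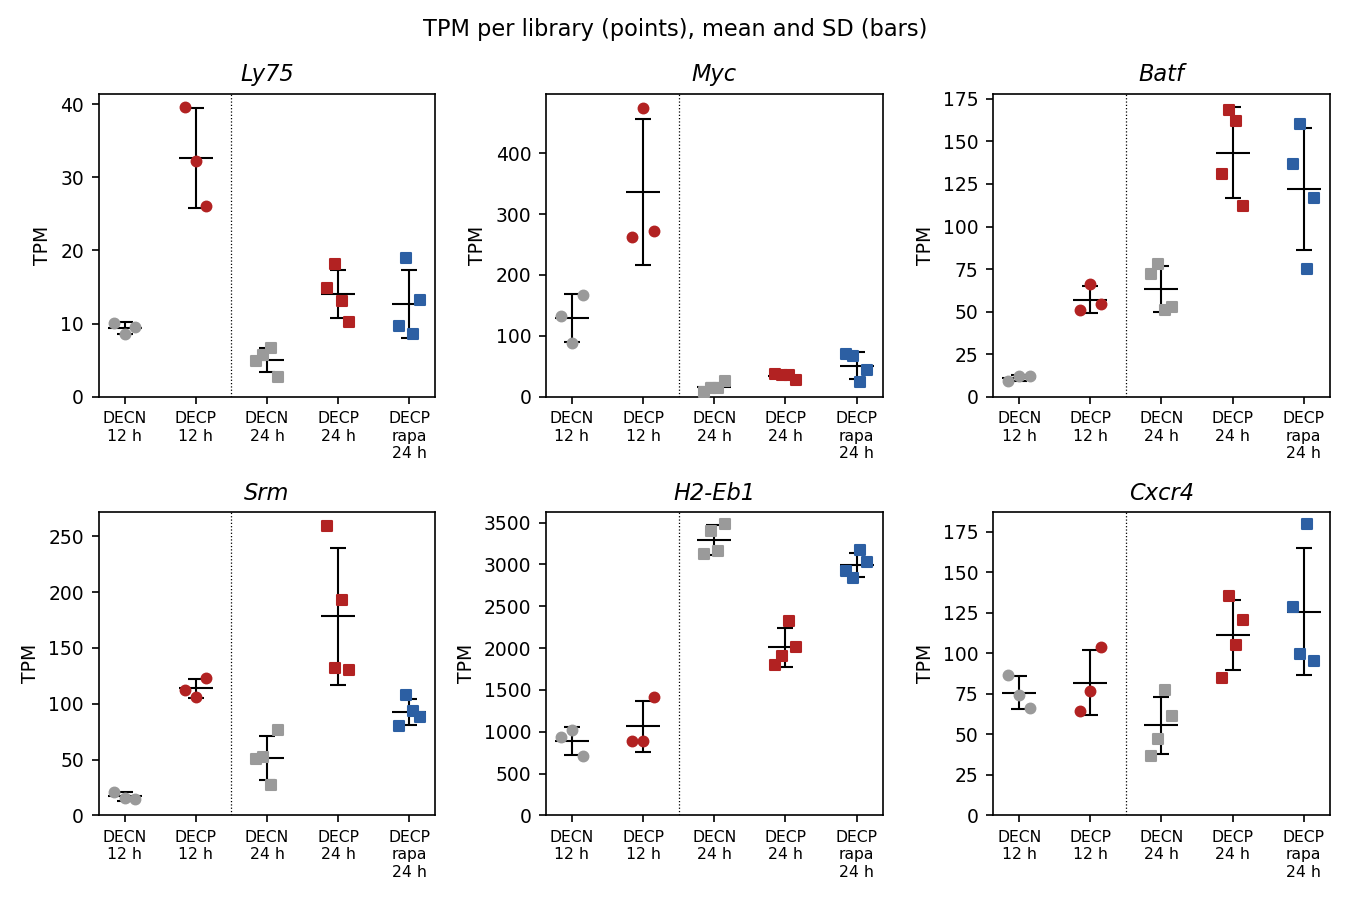
TPM of Ly75, Myc, Batf, Srm, H2-Eb1 and Cxcr4 in each library (points) with the mean and SD of each group, on linear axes from 0, with a dotted line between the separately made 12 h and 24 h tables. Srm stood at 114 TPM in DECP and 17.0 TPM in DECN cells at 12 h, and H2-Eb1 at 2007 TPM in DECP against 3291 TPM in DECN cells at 24 h.

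The first comparison asks which genes differ between DECP and DECN cells 12 h after the antibody. Srm, the spermidine synthase, rose 6.47-fold in DECP over DECN cells, from 17.0 ± 3.74 to 114 ± 8.34 TPM (n = 3 each, log2 change 2.69, SE 0.23, adjusted p = 0.0125). Batf, a transcription factor of the AP-1 family, rose from 11.2 ± 1.60 to 57.1 ± 7.92 TPM (log2 change 2.25, SE 0.24, adjusted p = 0.0125), and Npm1, the nucleolar protein nucleophosmin, from 275 ± 16.7 to 1114 ± 285 TPM (1.98, SE 0.20). In GRCm38 Srm (ENSMUSG00000006442) lies at 148591503 to 148594993 of chromosome 4, Batf (ENSMUSG00000034266) at 85686669 to 85709087 of chromosome 12 and Npm1 (ENSMUSG00000057113) at 33152287 to 33163206 of chromosome 11. Il1r2, a decoy receptor for interleukin 1, showed the largest rise, from 0.870 ± 1.06 to 27.5 ± 11.7 TPM (3.98, SE 0.52, adjusted p = 0.0179). Ccnd2, which encodes cyclin D2, rose from 26.5 ± 16.4 to 194 ± 57.6 TPM (2.98, SE 0.47, adjusted p = 0.0276) and Tnfrsf8, which encodes CD30, from 1.04 ± 0.147 to 15.2 ± 5.37 TPM (2.94, SE 0.32). The other large rises were Sap18b (3.88), whose reads may be shared with its close copy Sap18, the arginine methyltransferase Prmt1 (3.37), Zfp593 (2.71) and Sh2d6 (2.71). The largest falls were Zfp93 (-3.97), Ifit1bl1 (-3.63), Tlr6 (-3.48), Zcwpw1 (-3.08), Yod1 (-2.97), Lifr (-2.54), Crebrf (-2.49) and Arl8a (-2.46). Tlr6, a receptor for bacterial lipopeptides, went from 24.2 ± 6.25 to 1.23 ± 0.293 TPM.

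Lists for making ribosomes, protein and chaperones were higher in DECP cells at 12 h. Of 59 measured ribosome biogenesis genes 21 rose, and 51 rose when adjusted over the list alone, led by Lyar (2.03), Npm1 (1.98), Pno1 (1.88) and Ncl (1.24). The list's median log2 change was 1.24 (camera adjusted p = 2.49e-30, adjusted p = 0.0590 with an estimated correlation). Of 76 cytosolic ribosomal protein genes 38 rose (70 adjusted over the list alone), among them Rpl29 (1.39), Rpl7a (1.56) and Rpl4 (1.23), with a median of 1.17 and a camera adjusted p of 1.62e-40 (adjusted p = 0.159 with an estimated correlation). Reads of these genes are shared with their pseudogenes, which leaves the level of any single one uncertain. Translation factors and tRNA synthetases had 7 rises in 40 (24 adjusted over the list alone), including Eef1b2 (1.56) and Eif5a (1.42). The list had a median of 0.78 (4.45e-15, adjusted p = 0.154 with an estimated correlation). Heat shock and chaperonin genes had 10 rises in 19 (15 adjusted over the list alone), including the mitochondrial chaperonin genes Hspe1 (2.13) and Hspd1 (1.44) and the cytosolic Cct6a (1.76). Its median log2 change was 1.24 (4.18e-14, adjusted p = 0.154 with an estimated correlation). All 4 lists were higher in DECP under every scaling run.

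Metabolic lists were also higher in DECP cells at 12 h. Nucleotide and polyamine synthesis had 4 rises in 24 (13 adjusted over the list alone), Srm, Adsl (1.11), Nme1 (1.04) and Gart (1.44). Camera gave 3.60e-11 as the adjusted p, or adjusted p = 0.0590 with an estimated correlation. Amino acid uptake and one-carbon metabolism had 4 in 27 (8 adjusted over the list alone), namely the serine and folate enzymes Shmt2 (2.23), Mthfd1 (2.23) and Phgdh (1.43) and the amino acid transporter gene Slc7a5 (1.48). Camera gave 0.000291 as the adjusted p, or adjusted p = 0.159 with an estimated correlation. Oxidative phosphorylation had 2 in 59 (17 adjusted over the list alone), Ndufa10 (1.38) and Atp5g1 (1.09). The median change was 0.50 (3.19e-13, adjusted p = 0.204 with an estimated correlation). Glycolysis had 3 in 22 (10 up and 1 down adjusted over the list alone), Pkm (1.38), Hk2 (1.45) and Pgam1 (1.24). Camera gave 2.14e-05 as the adjusted p, or adjusted p = 0.237 with an estimated correlation. The unfolded protein response had 2 in 29 (7 up and 1 down adjusted over the list alone), the endoplasmic reticulum chaperone genes Hspa5 (0.95) and Pdia4 (2.06). Camera gave 0.00330 as the adjusted p, or adjusted p = 0.398 with an estimated correlation. Of 13 mitochondrially encoded transcripts limma called 0, with 3 up and 1 down at an unadjusted p under 0.05 and 3 up adjusted over the list alone (median 0.29, camera adjusted p = 0.0420, adjusted p = 0.662 with an estimated correlation). That call was lost without DECN replicate 2 (adjusted p = 0.289), DECN replicate 3 (adjusted p = 0.0640), DECP replicate 1 (adjusted p = 0.177) or DECP replicate 3 (adjusted p = 0.0962).

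The list of genes that answer CD40 and NF-kB was higher in DECP cells at 12 h. Of 29 measured 4 rose (12 up and 1 down adjusted over the list alone): Batf, Nfkbia (1.49), Nfkb2 (1.97) and Bcl2a1d (1.54), with a median of 0.56 (camera adjusted p = 3.25e-06, adjusted p = 0.0590 with an estimated correlation). The cytokine and STAT list, which shares Batf as its 1 rise in 22 (1 adjusted over the list alone), had a camera adjusted p of 0.0252 (adjusted p = 0.159 with an estimated correlation). It lost the call without DECN replicate 2 (adjusted p = 0.105) or DECP replicate 1 (adjusted p = 0.0513). G1/S and DNA replication had 1 rise in 41, Ccnd2 (3 adjusted over the list alone). They had a median of 0.16 (camera adjusted p = 0.0420, adjusted p = 0.720 with an estimated correlation). Its call was lost under quantile scaling (adjusted p = 0.119), median centring (adjusted p = 0.0517) or removal of a trend on transcript length (adjusted p = 0.0629), and without DECN replicate 1 (adjusted p = 0.362), DECN replicate 2 (adjusted p = 0.232) or DECP replicate 3 (adjusted p = 0.317). Germinal centre B cell genes were lower, with falls of the B cell transcription factors Ebf1 (-0.77) and Bach2 (-1.11) in 24 measured (5 falls adjusted over the list alone). Their median was -0.49 (0.00361, adjusted p = 0.398 with an estimated correlation). Of 19 FOXO targets limma called 0, with 1 up and 4 down at an unadjusted p under 0.05 and 1 fall adjusted over the list alone (median -0.47, camera adjusted p = 0.0165, adjusted p = 0.159 with an estimated correlation, and adjusted p = 0.0587 without DECN replicate 1).

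The remaining 14 lists were not past the threshold at 12 h. Single members that passed were Pmvk (-1.46) of cholesterol synthesis (camera adjusted p = 0.534), Junb (1.70) of the immediate early genes (0.509), Nfkbia and Ccnd2 of the light zone genes (0.0835), Derl3 (1.60) of the plasma cell genes (0.559), Gbp2 (2.52) of the interferon response (0.684), Bcl2a1d of the apoptosis regulators (0.252) and Apoe (-0.91) of the myeloid and dendritic cell genes (0.559). Apoe, abundant in macrophages, stood at 717 ± 76.9 TPM in DECP and 1358 ± 223 TPM in DECN cells. Camera adjusted p was 0.159 for G2/M and mitosis, 0.515 for dark zone genes, 0.252 for naive and memory B cell genes, 0.888 for T cell genes, 0.367 for stromal and endothelial genes, 0.367 for lysosome and autophagy and 0.352 for MHC class II presentation. Median and mean differed in sign for the plasma cell list (-0.05 and 0.14, test up) and the interferon list (-0.06 and 0.13, test up), and the T cell list (0.03 and 0.11) had a test in the down direction. Of the genes fixed beforehand, Myc stood at 336 ± 120 TPM in DECP and 129 ± 39.5 TPM in DECN cells with adjusted p = 0.0658. Also not past the threshold were Odc1 (log2 change 1.15, adjusted p = 0.0574), Irf4 (1.13, 0.121), Cd86 (-0.76, 0.0751), Foxo1 (-1.20, 0.158), Cd83 (-0.41, 0.278) and Cxcr4 (0.09, 0.875).

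In all, limma called 388 of 13429 genes at 12 h, 247 higher and 141 lower in DECP, of which 229 and 106 differed at least 2-fold. The groups did not overlap in 3533 genes, where chance gives 10%, and in all 388 called. The authors' deposited table listed 1460 genes at an adjusted p under 0.05, 982 higher and 478 lower, and held 369 of the 388. The count depended on each library: it was 0 without DECN replicate 1 and 0 without DECN replicate 2 (2139 and 2095 genes at an unadjusted p under 0.05), 94 without DECN replicate 3, and 58, 50 and 57 without DECP replicates 1, 2 and 3. It was also 30 without a filter, 595 with a filter at a TPM of 5, and 103 without the intensity trend.

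At 24 h the same groups were compared with 4 libraries each. Srm rose 3.49-fold, from 51.4 ± 20 TPM in DECN to 179 ± 61.4 TPM in DECP cells (log2 change 1.80, SE 0.29, adjusted p = 0.00386), and Odc1, the first enzyme of polyamine synthesis, from 111 ± 20.9 to 255 ± 62.1 TPM (1.19, SE 0.18, adjusted p = 0.00329). Batf rose from 63.6 ± 13.5 to 143 ± 26.7 TPM (1.17, SE 0.23, adjusted p = 0.0146) and Cxcr4, the chemokine receptor of dark zone cells, from 55.6 ± 17.5 to 111 ± 21.6 TPM (1.02, SE 0.25, adjusted p = 0.0414). H2-Eb1, a beta chain of MHC class II, fell from 3291 ± 178 to 2007 ± 228 TPM (-0.72, SE 0.08, adjusted p = 0.000949). H2-Eb1 (ENSMUSG00000060586) lies at 34305867 to 34316674 of chromosome 17 and Cxcr4 (ENSMUSG00000045382) at 128588199 to 128592293 of chromosome 1. The largest rises were Gnaz (2.40), Tmed6 (2.39), Gsto1 (2.33), Mtfp1 (2.05), the uridine-cytidine kinase gene Uck2 (2.05), Rpp40 (2.00), Ska1 (1.89) and Adgrl3 (1.85). Gnaz, an alpha subunit of a G protein, went from 1.78 ± 0.971 to 13.1 ± 1.39 TPM. The largest falls were Cerkl (-2.41), Dnase1 (-2.38), Mst1 (-2.24), Endou (-2.01), Acp5 (-1.94), Gh (-1.87), Ap3m2 (-1.72) and Rnf122 (-1.69).

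Lists of growth and division were higher in DECP cells at 24 h. Ribosome biogenesis had 17 rises in 59 (28 adjusted over the list alone), including Nop58 (1.05), Npm1 (1.08), Gar1 (1.35) and Ncl (1.03). The median lay at 0.67 (camera adjusted p = 4.48e-18, adjusted p = 0.0155 with an estimated correlation). Nucleotide and polyamine synthesis had 10 in 24 (19 adjusted over the list alone), including Pfas (0.93) and Paics (0.78) of purine synthesis. The list had a median of 0.87 (3.86e-15, and 0.00484 as the adjusted p with an estimated correlation). Heat shock and chaperonin genes had 14 in 19 (16 adjusted over the list alone), including Hsp90ab1 (0.90), Cct6a (1.32) and Tcp1 (0.81). Its median log2 change was 0.81 (8.49e-18, adjusted p = 0.0155 with an estimated correlation). Of 41 G2/M and mitosis genes 9 rose (24 adjusted over the list alone), such as the cyclin gene Ccnb1 (1.56, from 50.8 ± 16.4 to 155 ± 68.1 TPM), Ccnb2 (1.09), Birc5 (1.02) and Top2a (0.72). The median change was 0.77 (3.14e-14, adjusted p = 0.0155 with an estimated correlation). Translation factors had 10 in 40 (18 adjusted over the list alone), including Eif4a1 (1.01) and Hars (1.13). Camera gave 6.36e-11 as the adjusted p, or adjusted p = 0.0155 with an estimated correlation. G1/S and DNA replication had 5 in 41 (14 adjusted over the list alone), including the ribonucleotide reductase genes Rrm1 (0.98) and Rrm2 (0.71). Camera gave 6.71e-09 as the adjusted p, or adjusted p = 0.0545 with an estimated correlation.

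Of 59 oxidative phosphorylation genes 11 rose at 24 h (19 up and 1 down adjusted over the list alone), such as Atp5f1 (0.60) and Uqcrb (0.68). They had a median of 0.30 (camera adjusted p = 1.57e-12, adjusted p = 0.0684 with an estimated correlation), and of 0.13 under quantile scaling (adjusted p = 0.000311). Glycolysis had 5 rises in 23 (11 up and 1 down adjusted over the list alone), including Ldha (0.83), Pgam1 (1.03) and Tpi1 (0.81). Camera gave 6.74e-05 as the adjusted p, or adjusted p = 0.0545 with an estimated correlation. Amino acid uptake and one-carbon metabolism had 1 in 25, Mthfd1 (0.95), with 5 up and 1 down adjusted over the list alone (0.0134, adjusted p = 0.0545 with an estimated correlation). Dark zone genes had 5 rises in 18, among them Ccnb1, Ccnb2 and Cxcr4, and 2 falls (7 and 2 adjusted over the list alone). Their median was 0.59 (0.00607, adjusted p = 0.275 with an estimated correlation). The unfolded protein response had 1 rise in 29, Canx (0.52), with 3 up and 1 down adjusted over the list alone (0.00553, adjusted p = 0.282 with an estimated correlation, adjusted p = 0.108 under quantile scaling). Of 75 cytosolic ribosomal protein genes 4 rose, including Rps2 (0.71) and Rpl14 (0.56), and Fau fell (-0.42), with 6 up and 1 down adjusted over the list alone. The median lay at 0.10 (0.00168, adjusted p = 0.581 with an estimated correlation). That call was lost without DECN replicate 1 (adjusted p = 0.0904), DECP replicate 1 (adjusted p = 0.142) or DECP replicate 3 (adjusted p = 0.0624).

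Antigen presentation and several B cell lists were lower in DECP cells at 24 h. Of 14 MHC class II presentation genes 8 fell (9 adjusted over the list alone), led by H2-Eb1, H2-Aa (-0.68), H2-Ab1 (-0.56) and H2-Ob (-0.80). The list had a median of -0.59 (camera adjusted p = 1.58e-11, adjusted p = 0.0198 with an estimated correlation). Immediate early genes had 3 falls in 17 (8 adjusted over the list alone), Dusp2 (-0.84), Btg2 (-0.81) and Dusp5 (-1.30). Its median log2 change was -0.70 (6.53e-06, adjusted p = 0.0155 with an estimated correlation). Light zone genes had 2 in 22 (1 up and 6 down adjusted over the list alone), Fcer2a (-1.05), which encodes CD23 and went from 88.3 ± 13.6 to 42.1 ± 6.87 TPM, and Il4i1 (-0.93). Camera gave 0.000279 as the adjusted p, or adjusted p = 0.144 with an estimated correlation. Naive and memory B cell genes had 4 falls in 20 (7 adjusted over the list alone), Dusp2, Fcer2a, Fcmr (-1.04) and the transcription factor gene Klf2 (-1.47). Camera gave 7.80e-06 as the adjusted p, or adjusted p = 0.0545 with an estimated correlation. Germinal centre B cell genes had 2 in 24 (1 up and 5 down adjusted over the list alone), including Nuggc (-1.21). Camera gave 7.77e-05 as the adjusted p, or adjusted p = 0.131 with an estimated correlation. Lysosome and autophagy had 2 in 25 (2 adjusted over the list alone), the cathepsin genes Ctsa (-1.13) and Ctsz (-0.46). Camera gave 0.00805 as the adjusted p, or adjusted p = 0.0545 with an estimated correlation. FOXO targets had 1 in 20, Klf2 (1 adjusted over the list alone). Camera gave 0.00549 as the adjusted p, or adjusted p = 0.282 with an estimated correlation. The myeloid and dendritic list had 1 fall in 8 (1 adjusted over the list alone), Apoe (-1.07, from 1074 ± 52.6 to 517 ± 85.3 TPM). Camera gave 0.0218 as the adjusted p, or adjusted p = 0.128 with an estimated correlation. The call was lost without DECN replicate 2 (adjusted p = 0.0925) or DECP replicate 1 (adjusted p = 0.0666). The median of this list was -0.50, and myeloid and dendritic cells also carry MHC class II. Whether a different share of such cells in the sorted samples took part in the lower MHC class II values was not tested.

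The other 8 lists were not past the threshold at 24 h. Cholesterol synthesis had 1 rise in 24 (2 adjusted over the list alone) and a camera adjusted p of 0.0727. Members of others that passed were Batf and Icosl (0.421-fold, fell) of the CD40 and NF-kB list (camera adjusted p = 0.202), Batf, Fcer2a and Il4i1 of the cytokine list (0.646), Sec11c (0.58) and Tnfrsf13b (-0.77) of the plasma cell list (0.825, median -0.05, mean 0.05, test down), and Cd3d (1.29) and Lck (-0.90) of the T cell list (0.441). Others were Oasl1 (1.44) of the interferon response (0.567) and, among apoptosis regulators (0.260), Birc5 and Bmf (-1.94), a gene of a cell death activator that went from 5.95 ± 1.59 to 0.784 ± 0.235 TPM. Of 13 mitochondrially encoded transcripts limma called 0, with 1 up and 2 down at an unadjusted p under 0.05 (camera adjusted p = 0.922). Myc stood at 34.5 ± 4.75 TPM in DECP and 15.5 ± 7.30 TPM in DECN cells (1.21, SE 0.36, adjusted p = 0.0885) and did not pass. Nor did Cd83 (-0.49, 0.0626), Cd86 (-0.77, 0.0890), Slc7a5 (0.74, 0.122), Mki67 (0.77, 0.125) and Ccnd2 (0.91, 0.306).

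At 24 h limma called 517 of 12783 genes, 348 higher and 169 lower in DECP, of which 128 and 72 differed at least 2-fold. Quantile scaling gave 219 higher and 209 lower. The groups did not overlap in 1471 genes, where chance gives 2.857%, and in 508 of the 517 called. The authors' deposited table listed 1095 genes, 626 higher and 469 lower, and held 504 of the 517. The count was 308 without DECN replicate 2, 315 without DECN replicate 4, 274 without DECP replicate 1 and 298 without DECP replicate 3. Libraries carried either of 2 second index sequences, 2 per group each, and within AGAGTAGA limma called 5 genes and within TATCCTCT 0 (1325 at an unadjusted p under 0.05), with 2 libraries against 2. The median absolute deviation of a library from the rest of its group was 0.376 to 0.434 with TATCCTCT and 0.287 to 0.325 with AGAGTAGA. Mean correlations of residuals across groups were 0.014 to 0.031 for the same index and -0.030 to -0.014 for different ones. What the index marks is not known. List calls were lost within AGAGTAGA for ribosomal proteins (adjusted p = 0.315) and FOXO targets (adjusted p = 0.0647), and within TATCCTCT for the unfolded protein response (adjusted p = 0.0847) and the myeloid list (adjusted p = 0.135). Under quantile scaling the median of glycolysis went from 0.44 to 0.28 with the call kept.

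DECP cells from rapamycin-treated and untreated hosts were compared at 24 h to see which genes differ with the treatment. The drug was given to the hosts, and neither mTORC1 activity nor its action within the sorted cells was measured here. Tubb4b, a beta tubulin gene, fell from 392 ± 84.8 to 137 ± 17.7 TPM with rapamycin (n = 4 each, 0.354-fold, SE 0.17 on the log2 scale, adjusted p = 0.00210), Ccnb1 from 155 ± 68.1 to 53.5 ± 20.8 TPM (0.355-fold, SE 0.33, adjusted p = 0.0316) and Slc7a5 from 15.8 ± 3.38 to 6.01 ± 0.615 TPM (0.422-fold, SE 0.25, adjusted p = 0.0214). Cd83, a light zone marker, rose from 667 ± 95.3 to 1036 ± 181 TPM (0.63, SE 0.14, adjusted p = 0.0296) and Il4i1 from 132 ± 6.84 to 313 ± 87.6 TPM (1.19, SE 0.23, adjusted p = 0.0212). The other large falls were Fam166a (-1.64), the mitotic genes Ube2c (-1.49) and Bub1 (-1.36), Idi1 (-1.45) of isoprenoid synthesis, Fbxo8 (-1.31) and Coa6 (-1.31). The largest rises were Ephx1 (2.16), Cerkl (2.08), Zkscan5 (1.97), Zyg11b (1.95), Crlf2 (1.76), Ms4a4c (1.66), Ino80b (1.51) and Xrn1 (1.38). Myc (0.45, adjusted p = 0.658), Batf (-0.26, 0.701), Odc1 (-0.68, 0.0788) and Cxcr4 (0.15, 0.862) did not pass.

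Lists of metabolism and division were lower with rapamycin. Of 59 oxidative phosphorylation genes 19 fell (39 adjusted over the list alone), such as Uqcrb of complex III (-0.95, from 457 ± 56.6 to 236 ± 25.0 TPM), Atp5g3 (-0.78) and Cox7b (-0.69). The median change was -0.44 (camera adjusted p = 1.57e-28, adjusted p = 0.0159 with an estimated correlation), and -0.20 under quantile scaling (adjusted p = 9.34e-11). Cholesterol synthesis had 5 falls in 24 (10 adjusted over the list alone), including Idi1, Fdps (-1.28) and Msmo1 (-1.02). They had a median of -0.72 (1.60e-09, adjusted p = 0.0159 with an estimated correlation). G2/M and mitosis had 7 in 41 (18 adjusted over the list alone), including Cks2 (-1.30) and Cdca8 (-1.02). Their median was -0.72 (3.82e-14, adjusted p = 0.0159 with an estimated correlation). Heat shock and chaperonin genes had 8 in 19 (16 adjusted over the list alone), including Hspd1 (-1.07) and Hsp90aa1 (-0.75). The median lay at -0.59 (6.26e-15, adjusted p = 0.0233 with an estimated correlation). Translation factors had 4 in 40 (1 up and 16 down adjusted over the list alone), Eif2s1 (-0.76), Eif2s2 (-0.70), Eif4a1 (-0.54) and Eif5a (-0.48). Camera gave 9.78e-11 as the adjusted p, or adjusted p = 0.0159 with an estimated correlation. Ribosome biogenesis had 5 in 59 (11 adjusted over the list alone), including Pa2g4 (-0.80), Ncl (-0.68) and Gar1 (-0.84). The list had a median of -0.46 (5.19e-11, adjusted p = 0.0315 with an estimated correlation). Nucleotide and polyamine synthesis had 2 in 24 (5 adjusted over the list alone), Amd1 (-0.97) and Nme1 (-0.82). Camera gave 1.24e-07 as the adjusted p, or adjusted p = 0.0159 with an estimated correlation.

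Glycolysis had 3 falls with rapamycin in 23 genes (9 adjusted over the list alone), Ldha (-0.64), Tpi1 (-0.86) and Pgam1 (-0.89). Camera gave 9.71e-06 as the adjusted p, or adjusted p = 0.0356 with an estimated correlation. G1/S and DNA replication had 4 in 41 (5 adjusted over the list alone), including Pcna (-0.53) and Rrm2 (-0.74). Camera gave 3.37e-06 as the adjusted p, or adjusted p = 0.0820 with an estimated correlation. Dark zone genes had 3 in 18 (7 adjusted over the list alone), Bub1, Ccnb2 (-1.06) and Ccnb1, all genes of mitosis. Camera gave 3.84e-05 as the adjusted p, or adjusted p = 0.0935 with an estimated correlation. Amino acid uptake had 1 in 25 (1 adjusted over the list alone), Slc7a5. Camera gave 0.0134 as the adjusted p, or adjusted p = 0.0442 with an estimated correlation. Of 29 genes of the unfolded protein response limma called 0, with 7 down at an unadjusted p under 0.05 and 2 falls adjusted over the list alone (camera adjusted p = 0.00621, adjusted p = 0.281 with an estimated correlation, adjusted p = 0.473 under quantile scaling and adjusted p = 0.0785 without rapamycin replicate 2).

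Ribosomal protein genes and several B cell lists were higher with rapamycin. Of 75 cytosolic ribosomal protein genes 16 rose (50 adjusted over the list alone), including Rps18 (0.46, from 4527 ± 439 to 6205 ± 274 TPM) and Rps3 (0.38). Its median log2 change was 0.29 (camera adjusted p = 1.32e-30, adjusted p = 0.0679 with an estimated correlation). The list was higher under every scaling run, with the smallest median, 0.14, under quantile scaling. MHC class II presentation had 7 rises in 14 (10 adjusted over the list alone), including H2-Ob (0.90), H2-Eb1 (0.58) and H2-Oa (0.80). The median change was 0.50 (8.25e-14, adjusted p = 0.0159 with an estimated correlation). Myeloid and dendritic cells also carry MHC class II, and the list of their genes, not past the threshold, had a median of 0.45. A share of such cells in the sorted samples was not measured here. Light zone genes had 4 in 22 (6 adjusted over the list alone), Il4i1, Cd83, Fcer2a (1.04) and Nfkbie (1.30). They had a median of 0.50 (5.60e-09, adjusted p = 0.0339 with an estimated correlation). The cytokine list had 2 in 21 (2 adjusted over the list alone), Il4i1 and Fcer2a. Camera gave 0.000874 as the adjusted p, or adjusted p = 0.0339 with an estimated correlation. The CD40 and NF-kB list had 1 in 31, Nfkbie (2 adjusted over the list alone). Camera gave 0.000764 as the adjusted p, or adjusted p = 0.134 with an estimated correlation. Naive and memory B cell genes had 1 in 20, Fcer2a (2 adjusted over the list alone). Camera gave 0.00117 as the adjusted p, or adjusted p = 0.108 with an estimated correlation. Of 17 immediate early genes limma called 0, with 5 up at an unadjusted p under 0.05 (median 0.52, camera adjusted p = 0.000764, adjusted p = 0.0337 with an estimated correlation).

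The other 9 lists were not past the threshold with rapamycin. They held Ebf1 (0.75) and Eaf2 (-0.66) of the germinal centre list (camera adjusted p = 0.976, median 0.04, mean 0.02, test down), Jchain (-0.77) of the plasma cell list (0.751, median 0.00, mean -0.03, test down), Lck (0.71) of the T cell list (0.836, median -0.05, mean -0.19, test up), Apoe (0.79) of the myeloid list (0.0541, median 0.45, test up) and Ctsa (1.15) of the lysosome list (0.181). Limma called 0 members of 4 lists. These were the interferon response (0.0541, 2 genes at an unadjusted p under 0.05), apoptosis regulators (0.751, 5 genes, 3 up and 2 down, median -0.01, mean 0.12, test up), FOXO targets (0.836, 1 gene) and mitochondrially encoded transcripts (0.156, 2 genes).

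Rapamycin changed 279 of 12783 genes against untreated DECP, 84 higher and 195 lower, of which 26 and 30 differed at least 2-fold. The split depended on scaling, with 76 higher and 54 lower under quantile scaling, 53 and 232 under median centring, and 95 and 94 when TPM was rescaled without ribosomal protein genes. The groups did not overlap in 1145 genes, where chance gives 2.857%, and in 275 of the 279. The authors' deposited table listed 684 genes, 188 higher and 496 lower, and held 256 of the 279. The count was 125, 178 and 117 without DECP replicates 1, 2 and 3, and 108, 148 and 102 without rapamycin replicates 1, 3 and 4. It was 0 by limma without the intensity trend (1656 at an unadjusted p under 0.05), and 0 within each second index, AGAGTAGA (1448) and TATCCTCT (1054). Within TATCCTCT list calls were lost for amino acid uptake (adjusted p = 0.0551), naive and memory genes (adjusted p = 0.0579) and the unfolded protein response (adjusted p = 0.122). Under quantile scaling the median of G1/S went from -0.32 to -0.14 with the call kept.

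**Figure D2:**
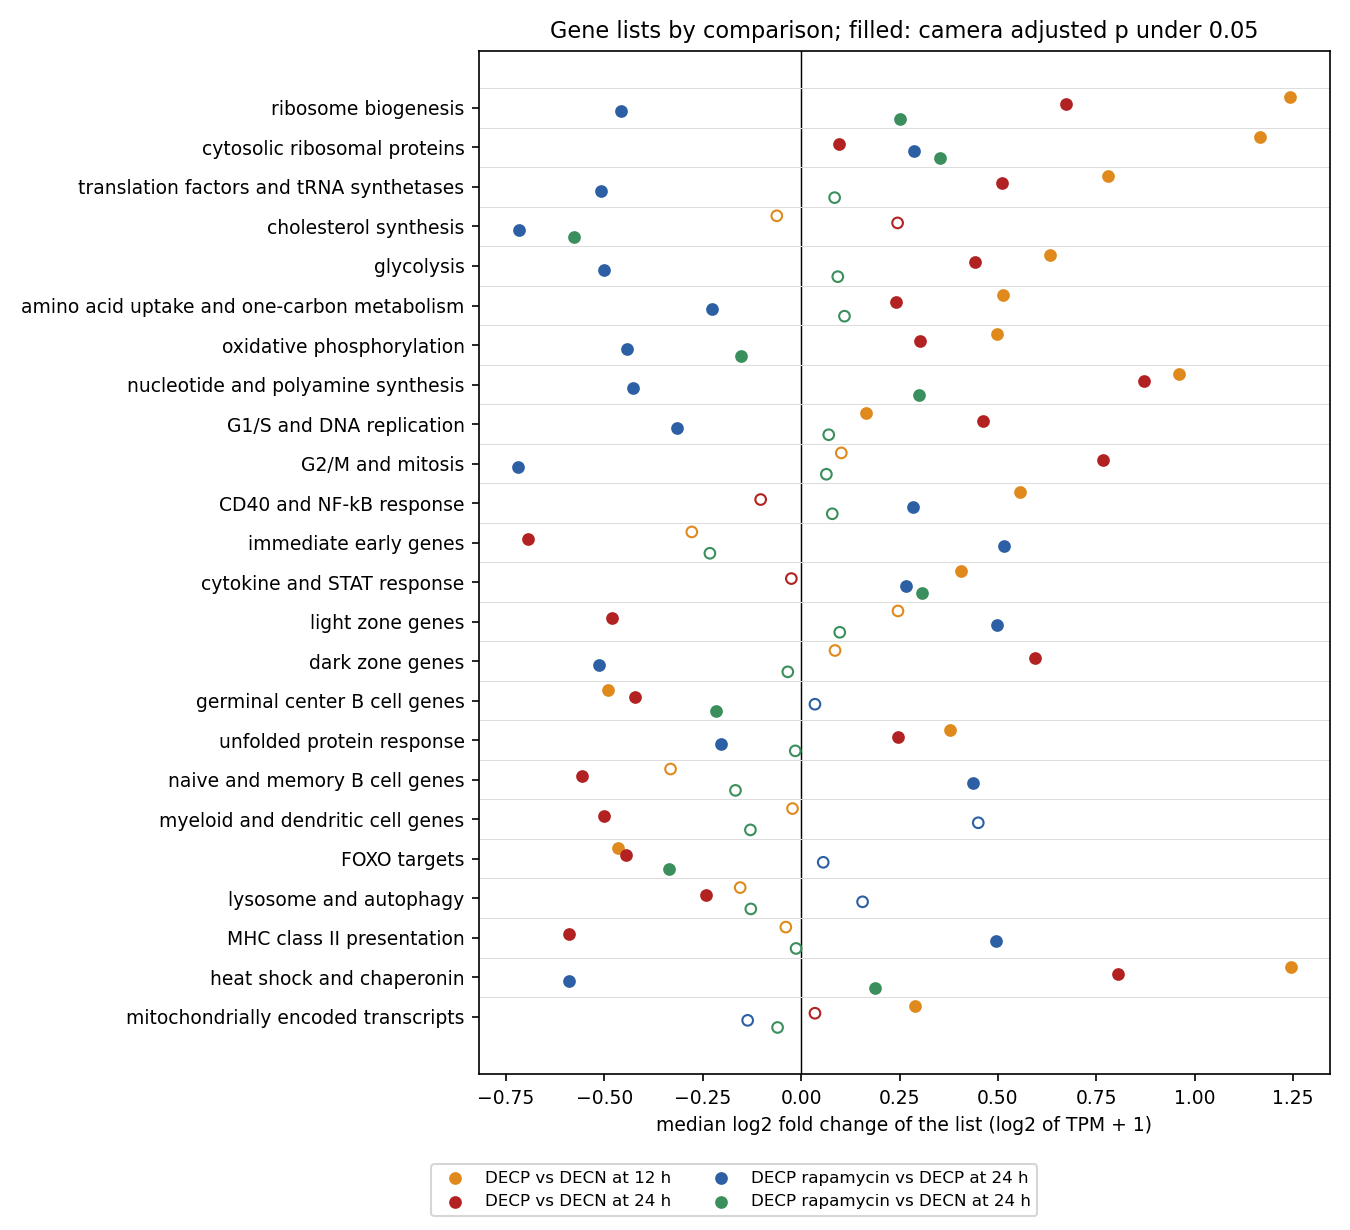
Median log2 fold change (on log2 of TPM + 1) of gene lists that passed the threshold in at least 1 of the 4 comparisons, one colour per comparison, filled where the camera adjusted p was under 0.05. MHC class II presentation stood at -0.59 in DECP against DECN at 24 h and at 0.50 with rapamycin against DECP, while ribosomal protein genes lay above 0 in all 4 comparisons.

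Of the genes that differed between DECP and DECN at 24 h, most went the other way with rapamycin. Among them 117 were higher in DECP and lower with rapamycin (5.31 for independent lists), such as Ccnb1, Ldha and Ncl, and 32 were lower in DECP and higher with rapamycin (1.11), such as H2-Eb1, H2-Ob and Fcer2a. By limma 0 were higher in both (2.29 for independent lists) and 0 lower in both (2.58), over lists that hold 2261 and 1776 genes at an unadjusted p under 0.05. Both comparisons share the untreated DECP libraries, so the values for independent lists are not those that unchanged groups would give. Unchanged groups simulated with this sharing gave 89.4% opposite signs, beside 90.9% observed. With the DECP libraries split so that none entered both differences, 83.8% of called genes had opposite signs on average over 6 assignments (69.5 to 93.8%), beside 50.4% simulated (45.8 to 55.3%). The simulation drew each gene independently, for 1 split and the 517 genes of smallest p. Its range therefore leaves out shifts that genes share, which would widen it. With the libraries split, the covariance of log2 changes was -0.052, beside 0.0004 simulated, and -0.145 beside -0.097 without the split. Genes higher in DECP went the other way in 89.5% (80.1 to 97.7% over the assignments) and genes lower in DECP in 73.4% (52.8 to 85.7%). For genes lower in DECP the low end lies within the simulated range of opposite signs.

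Rapamycin-treated DECP cells were also compared with DECN cells at 24 h. Myc stood at 51.3 ± 21.8 TPM in treated DECP and 15.5 ± 7.30 TPM in DECN cells (n = 4 each, log2 change 1.66, SE 0.36, adjusted p = 0.0452) and passed, although the groups overlapped. Cxcr4 rose from 55.6 ± 17.5 to 126 ± 39.1 TPM (1.17, SE 0.25, adjusted p = 0.0452). Crip1, a LIM domain protein gene, fell from 1669 ± 155 to 574 ± 146 TPM (-1.57, SE 0.17, adjusted p = 0.00215). Vim, an intermediate filament gene, fell from 195 ± 52.4 to 52.7 ± 28 TPM (-2.01) and Anxa2, of the annexins, from 297 ± 25.5 to 103 ± 31.2 TPM (-1.56). The largest rises were the folate carrier gene Slc19a1 (2.31), Gnaz (2.09), Ankzf1 (2.07), Lmo7 (2.02), Uck2 (1.90), Mtfp1 (1.78), Adgrl3 (1.68) and Ccnj (1.39). Other large falls were Mgll (-2.75), Msrb2 (-2.67), Igf2bp3 (-2.06), Gsn (-1.61) and Acyp1 (-1.58). The Myc call was lost in 11 of 12 runs with a library left out (adjusted p from 0.0541 without DECN replicate 4 to 0.139 without rapamycin replicate 1) and held without rapamycin replicate 3. That of Cxcr4 was lost in 10 of 12 (to 0.126 without rapamycin replicate 1) and held without DECN replicate 3 or DECP replicate 1. Batf (0.90, 0.0860), Ly75 (1.17, 0.0998), Ccnd2 (1.43, 0.158) and Slc7a5 (-0.50, 0.406) did not pass.

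Between treated DECP and DECN cells 9 lists passed, and none of the 9 did with an estimated correlation. Of 75 ribosomal protein genes 29 rose (66 adjusted over the list alone), including Rps18 (0.68, from 3886 ± 317 to 6205 ± 274 TPM), Rpl32 (0.56) and Rpl4 (0.48). Their median was 0.35 (camera adjusted p = 3.52e-48, adjusted p = 0.124 with an estimated correlation), and 0.21 under quantile scaling. Ribosome biogenesis had 1 rise in 59, Npm1 (0.61; 1 adjusted over the list alone). Camera gave 6.07e-05 as the adjusted p, or adjusted p = 0.311 with an estimated correlation. Nucleotide and polyamine synthesis had 1 in 24, the thymidylate synthase gene Tyms (0.83), with 5 adjusted over the list alone (6.07e-05, adjusted p = 0.124 with an estimated correlation). The cytokine list had 1 in 21, the kinase gene Pim1 (0.91), with 3 adjusted over the list alone (0.00975, adjusted p = 0.198 with an estimated correlation, and adjusted p = 0.0504 without rapamycin replicate 1). Chaperonin genes had 1 in 19, Hsp90ab1 (0.53; 1 adjusted over the list alone), with camera adjusted p = 0.00471, adjusted p = 0.466 with an estimated correlation and adjusted p = 0.0543 without rapamycin replicate 2. Germinal centre B cell genes had 4 falls in 24 (5 adjusted over the list alone), including Eaf2 (-0.91), Nuggc (-1.36) and Basp1 (-0.77). Camera gave 0.000119 as the adjusted p, or adjusted p = 0.311 with an estimated correlation. Limma called 0 members of 3 lists that were lower, cholesterol synthesis (7 of 24 down at an unadjusted p under 0.05, camera adjusted p = 2.18e-05, adjusted p = 0.124 with an estimated correlation), oxidative phosphorylation (11 of 59 down, 2 adjusted over the list alone, 6.07e-05, adjusted p = 0.466 with an estimated correlation, median -0.15, or -0.09 under quantile scaling and -0.06 without ribosomal protein genes) and FOXO targets (4 of 20 down and 1 up, 0.00818, adjusted p = 0.466 with an estimated correlation, adjusted p = 0.0587 without rapamycin replicate 2).

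The other 19 lists did not pass between treated DECP and DECN cells. Members that did included Eef1b2 (0.54) of the translation factors (camera adjusted p = 0.318), Pim1 of the CD40 list (0.124), Myc of the light zone genes (0.124), Cxcr4 of the dark zone genes (0.456, 1 up and 1 down), Cd3d (1.12) of the T cell genes (0.542), Oasl1 (1.20) of the interferon response (0.253), Bmf (-1.47) of the apoptosis regulators (0.456) and Gabarapl2 (-0.55) of the lysosome list (0.181). Limma called 0 members of the rest. With the count at an unadjusted p under 0.05, these were MHC class II presentation (2 genes, camera adjusted p = 0.780), G2/M and mitosis (3, 0.578), G1/S (9, 0.124), glycolysis (3, 0.780), amino acid uptake (4, 0.780), the unfolded protein response (4, 0.780, median -0.02, mean 0.05), immediate early genes (4, 0.124), naive and memory genes (3, 0.124), plasma cell genes (5, 0.542, median -0.06, mean 0.03), myeloid genes (1, 0.548) and mitochondrially encoded transcripts (4, 0.260).

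This comparison called 167 of 12783 genes, 99 higher and 68 lower, of which 34 and 32 differed at least 2-fold. The split was 49 higher and 54 lower under quantile scaling, 41 and 65 under median centring, and 146 and 43 when TPM was rescaled without ribosomal protein genes, which set the median of all genes at 0.103. The groups did not overlap in 1095 genes, where chance gives 2.857%, and in 165 of the 167. The authors' deposited table listed 527 genes, 222 higher and 305 lower, and held 146 of the 167. The count was 53, 89, 74 and 32 without DECN replicates 1, 2, 3 and 4, 110 and 107 without untreated DECP replicates 3 and 4, and 23, 82 and 34 without rapamycin replicates 1, 2 and 4. Within AGAGTAGA limma called 1 gene and within TATCCTCT 0 (1058 at an unadjusted p under 0.05). List calls lost within AGAGTAGA were ribosome biogenesis (adjusted p = 0.0978), the cytokine list (adjusted p = 0.0556), FOXO targets (adjusted p = 0.440) and chaperonin genes (adjusted p = 0.132). Without ribosomal protein genes the median of the germinal centre list went from -0.22 to -0.12 with the call kept.

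The differences between DECP and DECN cells at 12 h and 24 h were then set side by side over the 11848 genes tested at both times. Of these 84 rose at both times (6.95 for independent lists), among them Srm, Batf, Npm1, Ncl, Hspd1 and Hk2, 14 fell at both (1.74), including Apoe, Cd72, Ptprc and Rgs18, and limma called 0 in opposite directions (2673 and 2261 genes at an unadjusted p under 0.05). Of the 369 called at 12 h, 336 had the same sign at 24 h (91.1%). Pearson's r of the log2 changes was 0.358 and Spearman's rho 0.36, across genes, which are not independent replicates.

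**Figure D3:**
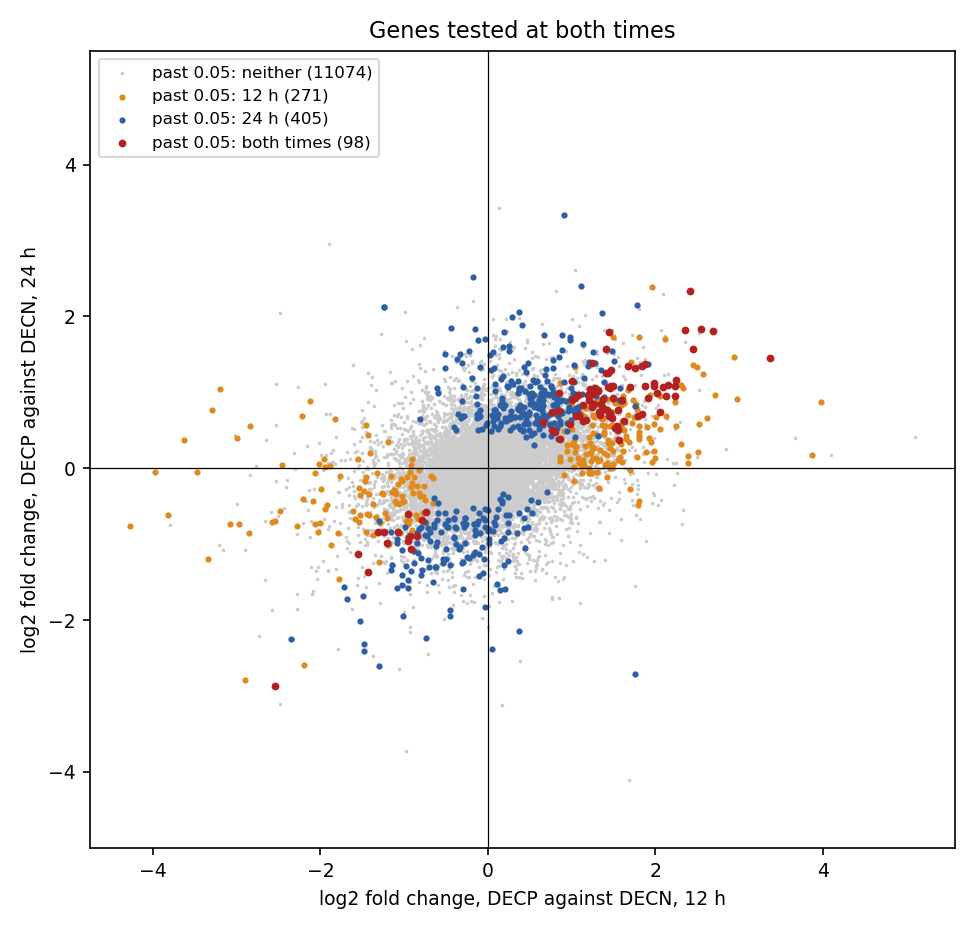
Log2 fold change of DECP over DECN cells at 12 h (horizontal) and 24 h (vertical) for 11848 genes, coloured by whether a gene passed the threshold at neither time (11074), at 12 h alone (271), at 24 h alone (405) or at both (98). The 98 genes lie in the quadrants of equal sign, 84 up and 14 down.

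The change of the difference from 12 h to 24 h was tested over all 18 libraries. Junb, an immediate early gene, went from 1.70 to -0.28 (difference -1.97, SE 0.35, adjusted p = 0.00875) and Nfkb2 from 1.97 to 0.08 (-1.89, adjusted p = 0.0285). Of 75 ribosomal protein genes 45 had a lower difference at 24 h (69 adjusted over the list alone), such as Rps15 (-1.53), Rpl8 (-1.45) and Rpl4 (-1.13), with a median of -1.05 (camera adjusted p = 7.03e-84, adjusted p = 0.0268 with an estimated correlation). The CD40 and NF-kB list had 2 in 29 (6 adjusted over the list alone), Nfkbia (-1.48) and Nfkb2, with a median of -0.80 (1.06e-08, adjusted p = 0.0268 with an estimated correlation). In all limma called 101 genes, 16 with a higher and 85 with a lower difference at 24 h. The count was 62 without DECN replicate 3 of 12 h and 66 without DECN replicate 2 of 24 h, and 206 under quantile scaling. Libraries of the 2 times also differed in the level of Y-linked genes, with Ddx3y at 245 TPM or more in all of 12 h and at 19.2 TPM or less in all of 24 h. Time is therefore not known to be all that sets them apart. The other genes and lists of this test are given further on, with the count from other splits of the libraries.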

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

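Of the tests in this part, that of the separate preparation of the 2 tables was chosen only after the result was seen. The difference between DECP and DECN cells changed from 12 h to 24 h for 101 genes, which is what brought them here, 16 with a higher and 85 with a lower difference at 24 h. Among the largest were Adgrl3 (2.30, from -0.45 to 1.85), the deubiquitinase gene Yod1 (2.24, from -2.97 to -0.73), Optc (1.83, from -0.33 at 12 h), Oasl1 (1.80, from -0.36 to 1.44) and Tenm1 (1.77, from -0.22 to 1.55). In the other direction were Sap18b (-3.70, from 3.88 to 0.18), Rpusd4 (-2.28, from 1.80 to -0.49), Pef1 (-2.23, from 1.80 to -0.44), Junb (-1.97, from 1.70 to -0.28) and Nfkb2 (-1.89, from 1.97 to 0.08). All values are differences of log2 changes, and the times stand in separate tables. Of 100 splits of the libraries 12 called at least as many genes, the real one included, with up to 486 in another split. All 11 others kept the 12 h groups whole and mixed the 24 h groups, and 85 drawn splits with neither time whole called at most 2 genes. The 11 splits carry the real difference at 12 h, so they cannot show how often chance gives as many genes. The count of 101 may rest on the difference at 12 h alone, and chance is not excluded by these splits. Y-linked genes were high in all libraries of 12 h and low in all of 24 h, so that the times may also differ in the sex of donors or hosts, which was not tested.

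Lists were marked for the same difference between times. Higher at 24 h were the medians of G2/M and mitosis (0.59, with Ttk at 1.59 and Top2a at 0.85, neither past the threshold), cholesterol synthesis (0.28), dark zone genes (0.33) and G1/S and DNA replication (0.24). Lower were ribosomal proteins (-1.05), CD40 and NF-kB (-0.80, with Nfkbia at -1.48 and Nfkb2 past the threshold), ribosome biogenesis (-0.56, with Nob1 at -1.38), MHC class II presentation (-0.53, with H2-DMa at -0.83, H2-Eb1 at -0.96 and H2-Ob at -0.81) and apoptosis regulators (-0.53). Also lower were immediate early genes (-0.51, with Junb and Cd69 at -1.73), amino acid uptake (-0.48), chaperonin genes (-0.40, with Hspe1 at -1.18), light zone genes (-0.36, with Nfkbia, Cd69 and Fcer2a at -1.50), the cytokine list (-0.31, with Fcer2a), oxidative phosphorylation (-0.24) and translation factors (-0.20, with Eef1b2 at -1.05). That made 16 lists, and 8 of 100 splits called as many, with up to 18, so that chance may account for the count. With an estimated correlation only ribosomal proteins and the CD40 list kept the call. The others lost it there, with adjusted p = 0.0617 for ribosome biogenesis and light zone genes, adjusted p = 0.0640 for amino acid uptake, immediate early genes, the cytokine list, apoptosis regulators and MHC class II presentation, and adjusted p = 0.218 for translation factors, cholesterol synthesis and G2/M. It was adjusted p = 0.306 for chaperonin genes, adjusted p = 0.347 for oxidative phosphorylation, adjusted p = 0.456 for dark zone genes and adjusted p = 0.579 for G1/S. Calls lost by leaving out a library were amino acid uptake (DECN 2, adjusted p = 0.0529, DECP 2, 0.0510, and DECP 3, 0.0520, of 12 h, and DECN 1, 0.0648, of 24 h) and apoptosis regulators (DECN 1, 0.0584, and DECP 1, 0.0842, of 12 h). G1/S lost it under quantile scaling (adjusted p = 0.199), and without DECN 3 (adjusted p = 0.511), DECP 1 (0.163) or DECP 2 (0.111) of 12 h and DECN 4 (0.0532) or DECP 1 (0.0825) of 24 h. Dark zone genes lost it without DECN 3 (adjusted p = 0.219), DECP 1 (0.172) or DECP 2 (0.0812) of 12 h and DECN 3 (0.0589) or DECP 1 (0.0994) of 24 h. Some medians also moved in such runs. Without DECP 1 of 12 h they were -0.205 for apoptosis regulators and 0.095 for G1/S. Without DECP 3 of 12 h that of amino acid uptake was -0.22. Not past the threshold were naive and memory genes (camera adjusted p = 0.0583, with Fcer2a past it), mitochondrially encoded transcripts (0.0875), the unfolded protein response (0.332) and nucleotide synthesis (0.929). The adjusted p was 0.569 for glycolysis, germinal centre (median 0.18, mean -0.02), plasma cell (median 0.08, mean -0.12), T cell, myeloid, interferon (with Oasl1 past it), FOXO and lysosome lists.

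In 7 cases a library lay far from the others of its group. Bcl6, the repressor that germinal centre cells need, stood at 22.1 TPM in DECN replicate 3 at 24 h and at 10.3 TPM in DECP replicate 1. Prdm1, a plasma cell regulator below the filter, stood at 1.05 TPM in DECN replicate 3 and 1.01 TPM in DECP replicate 3. Ccnd2 stood at 20.04 TPM in DECN replicate 3, Irf4 at 5.25 TPM in DECP replicate 2, and Ccnd3, which encodes cyclin D3, at 55.7 TPM in rapamycin replicate 2. In all 68 gene and group pairs were tested at a level where about 1 in 20 passes by chance.

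The higher ribosomal protein genes at 12 h were weighed against 3 technical explanations. Genes outside the list, matched on transcript length and level, had a median log2 change of 0.061 beside 1.17 for the list, which speaks against a better recovery of short transcripts. Pseudogenes, taken over all parent genes, changed by -667 TPM in sum while the ribosomal protein genes gained 18690 TPM. A net shift of reads from pseudogenes as a whole therefore does not account for the gain. Pseudogenes of ribosomal protein genes were not summed apart, so a shift from these that others offset cannot be excluded. The share of the list in DECN cells was 10.7 times higher at 24 h than at 12 h, in separately made tables. Whether the preparation of the libraries shaped the 12 h difference, or its smaller size at 24 h, cannot be told.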

How the results depend on the processing

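Of the alternatives, 23 were chosen after the data were seen, among them those without ribosomal protein genes and within a single second index. No gene, list or ratio past the threshold reversed under any, but some lists not past it changed sign (MHC class II presentation, rapamycin against DECN, from -0.01 to 0.06 under quantile scaling), and the balance of calls turned with scaling, for rapamycin against DECP from 84 higher and 195 lower to 76 and 54 (quantile), and for rapamycin against DECN from 99 and 68 to 49 and 54 (quantile) or 41 and 65 (median centring). The agreement of the times (r 0.358, 0.425 with a filter at a TPM of 5, 0.414 with a pseudocount of 5) and the opposite signs with rapamycin (83.8%, 83.0% at a TPM of 5) held. The unsplit 90.9% bears nothing on this, since unchanged groups gave 89.4%. At 12 h the count of 388 genes was 30 without a filter, 595 at a TPM of 5, 103 without a trend and 0 by limma with replicate number as a block (2662 at an unadjusted p under 0.05), and 1460 in the authors' deposited table. Left-out libraries gave 0 (2139) without DECN replicate 1, 0 (2095) without DECN 2, 94 without DECN 3, and 58, 50 and 57 without DECP 1, 2 and 3. At 24 h the 517 genes were 329 without a filter, 182 without a trend, 200 at 2-fold, 344 with the block, 5 within AGAGTAGA, 0 within TATCCTCT (1325) and 1095 in the deposited table, and 274 to 549 with a library left out (308 without DECN 2, 315 without DECN 4, 274 without DECP 1, 298 without DECP 3). The 279 of rapamycin against DECP were 164 without a filter, 130 under quantile scaling, 0 by limma without a trend (1656), 56 at 2-fold, 98 with the block, 121 with only those groups, 0 within AGAGTAGA (1448), 0 within TATCCTCT (1054) and 684 in the deposited table. They were 102 to 280 with a library left out (125, 178 and 117 without DECP 1, 2 and 3, and 108, 148 and 102 without rapamycin 1, 3 and 4). The 167 of rapamycin against DECN were 52 without a filter, 103 under quantile scaling, 106 under median centring, 22 without a trend, 66 at 2-fold, 41 with the block, 1 within AGAGTAGA, 0 within TATCCTCT (1058) and 527 in the deposited table. They were 23 to 173 with a library left out (53, 89, 74 and 32 without DECN 1 to 4, 110 and 107 without DECP 3 and 4, 23, 82 and 34 without rapamycin 1, 2 and 4). The 101 of the difference between times were 206 under quantile scaling, 45 without a trend, and 62 (without DECN 3 of 12 h) to 132 with a library left out (66 without DECN 2 of 24 h). Lists past the threshold with an estimated correlation were 0 of 15 at 12 h by camera (9 at an unadjusted p under 0.05), 7 of 20 at 24 h, 13 of 19 for rapamycin against DECP, 0 of 9 for rapamycin against DECN (4), where fry gave 4, and 2 of 16 for the difference between times, where fry gave 9. In the other comparisons fry lost 4 of the 15 calls at 12 h, 3 of the 20 at 24 h and 2 of the 19 for rapamycin against DECP. The Ly75 ratio at 24 h ranged from 2.44 (without DECN 4, exact permutation p = 0.0571, the groups still apart) to 3.15. Fewer libraries by construction lower the power of left-out and single-index runs, and libraries with TATCCTCT also spread more than those with AGAGTAGA. For the rest the cause was not tested. Every call of a named gene at 12 h and 24 h, 58, 81, 66 and 35 in the 4 comparisons, was lost under at least 1 alternative. Of the list calls 0 of 15, 7 of 20, 12 of 19 and 0 of 9, in the same order, were kept under every alternative. Correlations of residuals between libraries of the same replicate number ran from -0.119 to 0.122, and of other pairs from -0.152 to 0.129. At 12 h, where limma called 0 genes with the block, they ran from -0.031 to 0.122 and from -0.129 to 0.086. Replicate numbers thus gave no clear sign of pairing. With 3 or 4 libraries per group this check cannot exclude it, and the hosts received a mixture of DECP and DECN cells. A count model per library, transcript values and single Ly75 transcripts were not run, since per-library counts and transcripts were not held. Limits from depth were not analysed here, as TPM keeps none.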

Other observations

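Of the tests in this part, those of TOP messages, of donor variants and the criterion for donor segments were chosen only after the result was seen. Messages that begin with a 5-prime TOP sequence, other than ribosomal proteins, are known targets of translation control by mTORC1. Of 20 such genes 7 rose in DECP over DECN cells at 12 h (median 0.78), 4 rose at 24 h (median 0.21) and 7 rose in rapamycin-treated DECP over DECN cells (median 0.28). With rapamycin against untreated DECP their median was 0.056 (quartiles -0.18 to 0.28), and Eef1a1 rose (0.36).

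Ribosomal protein genes made up 1.68 ± 0.164% of TPM in DECN and 3.56 ± 0.596% in DECP cells at 12 h (SD, n = 3 each). At 24 h, in a separate table, they made up 18 ± 1.15% in DECN, 19.2 ± 1.66% in DECP and 23.0 ± 0.894% in rapamycin-treated DECP cells (n = 4 each). Mitochondrially encoded transcripts made up 2.78% and 2.69% at 12 h in DECN and DECP, and 3.18%, 3.28% and 2.84% at 24 h in DECN, DECP and rapamycin-treated DECP cells.

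Y-linked genes stood at different levels in the 2 tables. In the 6 libraries of 12 h Ddx3y ran from 245 to 442 TPM, Eif2s3y from 89.5 to 230, Kdm5d from 59.0 to 89.9 and Uty from 134 to 288. In the 12 libraries of 24 h Ddx3y ran from 0.139 to 19.2 TPM, Eif2s3y from 1.14 to 31.2, Kdm5d from 7.41 to 12.7 and Uty from 5.70 to 16.9. Of these DECN replicate 1 (Ddx3y 19.2, Eif2s3y 22.1) and DECN replicate 2 (Ddx3y 11.7, Eif2s3y 31.2) stood apart, with at most 1.61 and 5.21 TPM in the 10 others. The sex of the donors is not given.

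Higher ribosomal protein genes with rapamycin were weighed against 3 explanations. The list median lay 0.264 above the median of all genes, and 0.138 above it under quantile scaling, the smallest distance, with the call kept under scaling but lost with an estimated correlation (adjusted p = 0.0679). Scaling may thus account for part of the rise, not for all of it. The 313 genes matched on length and level had a median of -0.216 (quartiles -0.478 to 0.081), beside 0.29 for the list. Taken for each ribosomal protein gene in turn, the medians of its matched genes had a median of -0.029. Both values speak against recovery of short transcripts. The TOP messages, at 0.056, leave open whether a shared response of such messages took part.

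Genes that differed in the same direction at both times were weighed against the origin of the donor cells, which by design differ in Ly75 and in the CD45 alleles of Ptprc. Of the 98 genes 3.06% lay within 10 Mb of Ptprc or Ly75, namely Ptprc, Rgs18 and Ly75, beside 1.22% of the other genes (odds ratio 2.56, Fisher's exact p = 0.120). Local differences within 10 Mb of these 2 genes therefore do not account for most of the pattern. Longer donor segments, segments elsewhere and effects on distant genes were not tested. Ptprc, Rgs18 and Ly75 may differ through donor variants, which values per gene cannot show. Of the sex-linked genes 1, Uty, was apart in the same direction at both times, while Ddx3y, Eif2s3y and Kdm5d overlapped between the groups at 1 or both times, although all 4 had lower means in DECP cells. At 24 h only DECN replicates 1 and 2 held Ddx3y and Eif2s3y at more than a few TPM. The 3 overlapping genes argue only against a complete difference of sex between the groups at both times. A partial difference, from mixed donors or hosts, cannot be excluded, since Eif2s3y was also apart at 12 h. Those 2 libraries are also the DECN libraries of 24 h with second index AGAGTAGA. What sets them apart was not tested, and whether the DECN libraries of 24 h are independent is not known.

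The libraries were also split in all ways within a comparison, and in 100 drawn ways across the times. At 12 h the real split was 1 of 10 to call as many genes (388, highest other 1) and 1 of 10 to call as many lists (15, highest other 12), and 10 splits are too few to exclude chance. At 24 h DECP against DECN was 1 of 35 for genes (517, highest other 2) and 2 of 35 for lists (20, highest other 20). Rapamycin against DECP was 1 of 35 for genes (279, highest other 3) and 3 of 35 for lists (19, highest other 20), and rapamycin against DECN 1 of 35 for genes (167, highest other 2) and 4 of 35 for lists (9, highest other 15). If the libraries of a group are independent, chance does not account for the counts of genes at 24 h. The labels do not say that they are, and 1 of 35 is the smallest share possible. For lists chance is not excluded by these counts. Every other split that called as many lists at 24 h exchanged a single library per group and so kept only part of the real contrast. Splits that mixed the groups 2 and 2, which cancels the contrast, still called up to 8, 10 and 7 lists in the 3 comparisons. Lists can therefore pass at the preset correlation without a difference between the groups. The agreement of the times was 1 of 100 (0.358, highest other 0.224).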
